A study of Mus musculus with 2 samples.

How the data were processed

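Spatial transcripts were measured by MERFISH, an imaging method that reads barcoded RNA molecules one by one in tissue, in 2 sections of mouse liver that the labels place in 1 group as replicates 1 and 2. Per the labels' protocols, livers were snap frozen, embedded and cut on a cryostat, then fixed on slides for the Vizgen instrument. The labels do not say whether the sections came from separate animals. With section as a block, p-values reflect counting error and how far differences between places disagree between these sections, which may be technical. This spread is moderated across genes, so the SE of a gene can be smaller than its own gap between sections. The p-values cannot be read as spread between animals. Both labels carry the tag 2d, which was not interpreted. The series' design text describes treated mice with liver metastases, which does not match these labels. No label ties either section to a treatment, so none was assigned. With 1 group there was no comparison between groups, and all tests compared places within sections.

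The deposited tables hold raw counts per segmented cell for 500 genes and 50 blank barcodes, which name no gene and were left out of totals and tests. Blank barcodes took 0.910% of counts in section 1 and 0.390% in section 2. In kept cells the highest blank held 268 and 410 counts, which 186 and 102 of the 500 genes exceeded. The mean blank held 51.3 and 19.2 counts, which 380 and 404 genes exceeded. Blanks were not binned by position or neighbours, so those tests have no blank background. The deposited cell tables also hold volumes, positions and an image signal per stain; their headers name no unit of length, and µm was assumed from the sizes of cells. Recounting the deposited transcripts by cell gave the same counts for all 26037 cells of section 1 and all 85929 cells of section 2. The decoding and segmentation software and their versions are not given in the sources used here.

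Cells with at least 10 counts and a volume of at least 50 cubic µm were kept. The planned minimum of 20 gave way to 10 by a rule set in advance, because 30.8% and 7.85% of cells with any count reached 20. Counts were scaled to the median total and log-transformed, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave clusters (Python 3.11.15, scikit-learn 1.9.0, leidenalg 0.10.2). All kept cells were clustered together, in place of the planned subsample. No doublet caller was run. Classes were named from markers fixed before the data were examined, as were the gene lists, the candidate landmarks with the rule that picks them and the planned comparisons, and "-like" marks such names.

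The scoring rule that turns markers into names was changed after its outcome had been seen. The first rule asked for markers at 2-fold over the 25th percentile of clusters, and it named 43.7% of section 1 and 39.1% of section 2 hepatocyte-like, with 41.4% of section 2 unnamed. The rule used here joins clusters whose profiles correlate at 0.95 or more and asks for at least 3 markers at 1.5-fold over the median of joined groups, with at least 1 among the 10 leading genes. Results under the first rule are among the alternatives.

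A position score was computed for each cell from at least 5 hepatocyte-like cells within 50 µm, the cell itself left out, as the log2 ratio of pericentral (Glul, Cyp2e1, Gulo) to periportal (Pck1, Ass1, Hsd17b13) landmark counts. Landmarks were the first 3 candidates per side with a mean of at least 0.05 counts per hepatocyte-like cell in both sections. Cells were split within each section into 3 equal bins of this score, or of the share of blood-forming-like neighbours (erythroid-like and monocyte_neutrophil-like). Only kept cells counted as neighbours, and cells with fewer than 5 of them within 50 µm were left out. Comparisons of places thus cover only cells with enough kept cells around them. A bin held 889 or 890 hepatocyte-like cells by position in section 1 and 3716 in section 2, 212 and 247 or 248 macrophage_kupffer-like cells, and 1231 and 3868 or 3869 hepatocyte-like cells by neighbours. Raw counts were summed per section and bin, giving 6 sums with 2 residual degrees of freedom. Sums were tested with edgeR 4.0.16 (quasi-likelihood, TMM, section as a block, at least 50 counts, Benjamini-Hochberg at 0.05), and the contrast was the highest minus the lowest bin. Landmarks were left out of the tests of position. Log2 changes of genes in single sections are differences of log2 CPM with a prior count of 2. They can therefore both lie on the same side of the edgeR estimate. The SE was derived from the edgeR log2 change and its F statistic. Gene lists were tested with fry in limma 3.58.1 on log2 CPM with a prior count of 2, for change in 1 direction and, as the mixed test, in either. DESeq2 1.42.0 was an alternative. Endothelial-like and stellate_mesenchymal-like cells fell below the 200 cells per bin set in advance and were not tested.

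The edgeR step was tested on simulated data with 200 genes changed, equally many 2-fold and 1.5-fold, over 20 draws per comparison. Only genes with at least 50 counts entered, so the percentages called cover tested genes and not all 200 changed. A mean of 61.95 genes changed 2-fold was tested for hepatocyte-like cells by position, 69.75 near blood-forming-like cells and 28.75 for macrophage_kupffer-like cells. For hepatocyte-like cells by position the step called 77.1% of tested genes changed 2-fold and 44.1% of those changed 1.5-fold. Of its calls 3.07% were false. Near blood-forming-like cells these values were 77.1%, 42.0% and 3.19%. For macrophage_kupffer-like cells they were 42.3%, 17.6% and 2.92%. With no gene changed, 1 of 20 draws made a false call for macrophage_kupffer-like cells and 1 of 20 near blood-forming-like cells, and 0 of 20 did for hepatocyte-like cells by position.

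Neighbour pairs within 30 µm were set against 20 shuffles of class labels. Moran's I, a measure of spatial clustering, was computed on 50 µm squares with at least 5 kept cells, with blank barcodes as background. The text names up to 12 called genes per direction with the same sign in both sections, up to 4 members per list, and the 12 genes with the highest lower Moran's I. Intervals are exact and cover counting error only. The lists of fetal hepatocyte genes and of hypoxia and stress genes had under 3 tested members in each comparison and were not tested. Alternatives were other tools, scalings, filters, radii, bins and landmarks, and each section left out.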

Results

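The transcripts of 500 genes were imaged in 2 mouse liver sections of 1 group. Section 1 held 26037 segmented cells with 428386 gene counts, and section 2 held 85929 cells with 475382 counts. The median over all cells was 4 counts in section 1 and 3 in section 2. With at least 10 counts, 9209 cells (35%) were kept in section 1 with a median of 27 counts, and 16290 (19%) in section 2 with a median of 15. Kept cells were spread unevenly. Among 250 µm tiles with at least 20 cells, 12.6% in section 1 and 33.8% in section 2 kept under 5% of their cells. Hp, which encodes the acute phase protein haptoglobin, took 8.0% of the counts of kept cells in section 1 and 16.2% in section 2. Igfbp2 took 3.89% and 13.8%, and Fn1, which encodes fibronectin, 8.59% and 3.10%. F2, which encodes prothrombin, took 5.68% and 5.23%. The proliferation marker Mki67 had a 6.55-fold and the granulocyte receptor gene Csf3r a 4.36-fold higher share in section 1, and Gstm1 a 6.96-fold higher share in section 2. Of 215 genes with at least 100 such counts in both sections 72 differed by over 2-fold, and Pearson's r of their log2 shares was 0.813. Spearman's rho across all 500 genes, which are not independent replicates, was 0.889.

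Hepatocyte-like cells were the most frequent class, with 47.6% of kept cells in section 1 and 77.3% in section 2 (62.4% ± 21.0, SD, n = 2). Erythroid-like cells, marked by Epor and Car2, made up 14.7% and 2.31% (8.49% ± 8.74, SD, n = 2). Macrophage_kupffer-like cells, marked by Clec4f, Adgre1 and Csf1r, made up 12.3% and 5.40%. Monocyte_neutrophil-like cells made up 7.66% and 7.25%, stellate_mesenchymal-like cells 5.15% and 3.19%, and endothelial-like cells 4.03% and 0.933%. B_lineage-like cells made up 2.20% and 0.460%, and 6.42% and 3.19% stayed unnamed. Most hepatocyte-like cells of section 1 lay in cluster 0, led by Fn1, Fga and Fgb, and most of section 2 in clusters 1 to 5, in which Igfbp2, Gjb1 and Hp were among the leading genes. The hepatocyte-like share rested on the rule for naming clusters and on their resolution, since the first rule gave 43.7% and 39.1%, and resolution 2.0 gave 37.9% and 38.9%. Hepatocyte-like and unnamed cells together made up 54.0% and 80.5% under both rules, and 50.9% and 86.8% at resolution 2.0.

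**Figure D1:**
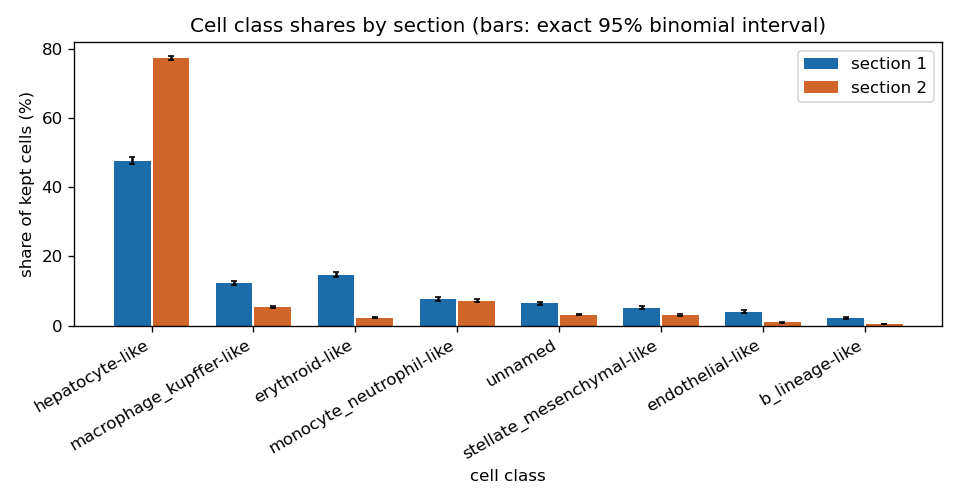
Share of kept cells (%) per cell class in each section, with exact 95% binomial intervals as bars. Hepatocyte-like cells reached 47.6% in section 1 and 77.3% in section 2, and erythroid-like cells 14.7% and 2.31%.

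Liver lobules run from portal to central veins, and hepatocyte-like cells differed along this axis. On the pericentral side Rnase4 was higher by 3.01 on the log2 scale (SE 0.33, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 9.1e-17). Lect2 was higher by 1.98 (SE 0.31) and Cyp1a2, a drug-metabolising enzyme, by 1.84 (SE 0.36). The Wnt targets Axin2 and Tbx3 were higher by 1.29 (SE 0.27) and 1.80 (SE 0.40), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.06 (SE 0.25). Higher on the periportal side were Cyp2f2, with a log2 change of -2.46 (SE 0.19), and Hal, which degrades histidine, with -1.58 (SE 0.34). The urea cycle gene Arg1 was too, with -0.85 (SE 0.19). In sections 1 and 2 Cyp2f2 stood at -1.89 and -3.27 and Hal at -0.86 and -1.69. Rnase4, Lect2, Cyp1a2, Axin2, Tbx3 and Hal each held fewer counts in hepatocyte-like cells than the highest blank in all kept cells, in both sections. Cyp7a1 and Cyp2f2 did so in section 2 only. Among genes named below, Sox9, Wnt2, Col3a1, Lhpp and Oat also lay below the highest blank in both sections.

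In all, 30 of 313 genes passed the edgeR test, 17 higher and 13 lower on the pericentral side, and all 30 had the same direction in both sections. Among the landmarks that defined the axis, Glul was 2.68-fold and 2.64-fold higher on the pericentral side in sections 1 and 2, and Pck1 was 1.82-fold and 1.64-fold higher on the periportal side. Of 12 tested pericentral genes 9 rose, and 9 also when adjusted over the list alone (fry adjusted p = 0.047). Of 8 periportal genes 4 fell, and 6 when adjusted over the list alone (fry adjusted p = 0.011). Of 8 Wnt genes Tbx3, Axin2 and Wnt2 rose, 3 also when adjusted over the list alone, and the list did not pass (fry adjusted p = 0.17). Of 3 extracellular matrix genes Col3a1 and Col1a1 rose by 0.90 (SE 0.29) and 0.64 (SE 0.18) and Fn1 fell by 0.23 (SE 0.07), with the same calls when adjusted over the list alone (fry adjusted p = 0.048). The Notch list passed (fry adjusted p = 0.026) with 1 of 5 members called, also when adjusted over the list alone, which was Sox9 at -1.47 (SE 0.37), with a median of -0.03 and Notch1 and Notch4 at 0.31 (SE 0.20) and 0.32 (SE 0.31). Sox9, also on the periportal list, had its highest level in unnamed cells in section 1 and in stellate_mesenchymal-like cells in section 2. Of 4 urea and nitrogen genes Oat rose and Arg1 and Hal fell, and 1 rose and 3 fell when adjusted over the list alone (fry adjusted p = 0.052). Of 7 cell cycle genes 0 passed edgeR, 2 fell when adjusted over the list alone, and the list did not pass (fry adjusted p = 0.054). Median and mean differed in sign for the lists of mature hepatocyte genes (0.20 and -0.19), gluconeogenesis (0.10 and -0.05) and xenobiotic enzymes (0.21 and -0.05), and for blood niche signals the median was -0.02 while fry pointed up, and none of these lists passed that one-way test. By fry's mixed test, for change in either direction, 13 of 16 lists passed, among them mature hepatocyte genes (adjusted p = 0.011), gluconeogenesis (0.045), xenobiotic enzymes (0.0093) and blood niche signals (0.020). In both sections Col1a1 and Col3a1 had their highest level in stellate_mesenchymal-like cells, and Axin2, Tbx3 and Lhpp in unnamed cells. Oit3 and Wnt2, which were higher by 0.81 (SE 0.22) and 1.10 (SE 0.38), had theirs in endothelial-like cells in both sections. Wnt2 stood at 0.42 in section 1 and 1.56 in section 2. Cyp1a2 and Arg1 were highest in hepatocyte-like cells in section 1, but in endothelial-like and B_lineage-like cells in section 2. Without the section as a block 0 genes passed edgeR, with 10 at an unadjusted p under 0.05 (DESeq2 with the block called 19), and only the pericentral and periportal lists passed. With periportal landmarks alone 2 genes passed, and with cell volume as the offset, which moved the median log2 change to -0.17, 11 genes were higher and 34 lower.

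**Figure D2:**
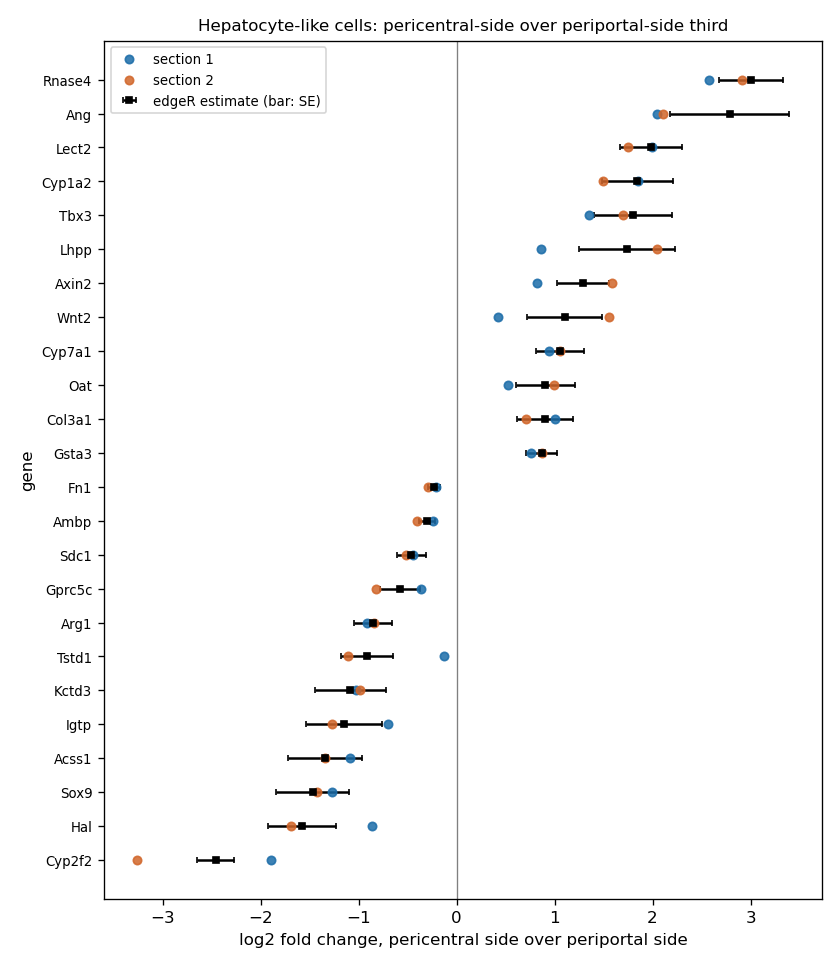
Log2 fold change (pericentral over periportal side) of the called genes with the largest changes in hepatocyte-like cells. Squares with bars are edgeR estimates with SE, and circles are the sections, with Rnase4 at 3.01 and Cyp2f2 at -2.46.

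Among macrophage_kupffer-like cells Clec4f, a Kupffer cell lectin, was lower on the pericentral side. Its log2 change was -1.26 (SE 0.33, edgeR adjusted p = 0.028), with -1.68 in section 1 and -0.61 in section 2. Cyp2f2, which had its highest level in hepatocyte-like cells in section 1 and in monocyte_neutrophil-like cells in section 2, was lower too, at -1.89 (SE 0.54, edgeR adjusted p = 0.039). Of 130 genes 0 were higher and 2 lower by edgeR, and 14 had an unadjusted p under 0.05. No list passed fry's one-way or mixed test, and that of interferon genes had a median of 0.15 and a mean of -0.01. DESeq2 called 0 genes, with 3 at an unadjusted p under 0.05, and edgeR called 0 without TMM (13 unadjusted) and 0 without the section as a block (0 unadjusted). With 5 bins 2 other genes passed, both higher, and Clec4f and Cyp2f2 did not.

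Endothelial-like cells made up 3.08% of periportal-side and 5.60% of pericentral-side cells in section 1, and 0.666% and 1.05% in section 2. Erythroid-like cells ran the other way, with 13.6% and 8.74% in section 1 and 2.71% and 1.78% in section 2. The log2 ratios of pericentral to periportal side were 0.76 ± 0.14 (SD, n = 2) for endothelial-like and -0.62 ± 0.02 (SD, n = 2) for erythroid-like cells. Stellate_mesenchymal-like cells had ratios of 0.81 in section 1 and -0.29 in section 2. With a radius of 30 µm the erythroid-like ratios were -0.24 and -0.78 in sections 1 and 2, and with 100 µm -0.70 and -1.22. The endothelial-like ratios were 0.56 and 0.50 at 30 µm, and 0.77 and 0.22 at 100 µm. The agreement between sections thus varied with the radius. No test was run on these 2 sections.

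Hepatocyte-like cells with many blood-forming-like neighbours held more Cd24a, by 0.90 on the log2 scale (SE 0.18, edgeR adjusted p = 7.1e-05), Car2, a carbonic anhydrase, by 0.85 (SE 0.19), Epor, the erythropoietin receptor, by 0.75 (SE 0.21), and Mki67 by 0.76 (SE 0.15). Cyp2f2 was higher by 0.67 (SE 0.16), with 0.29 in section 1 and 1.25 in section 2. The pericentral genes Rnase4, Cyp2e1, Glul and Gulo were lower, at -1.02 (SE 0.28), -0.70 (SE 0.14), -0.44 (SE 0.12) and -0.39 (SE 0.12). Cyp2e1 stood at -0.34 in section 1 and -1.03 in section 2. Of these pericentral genes Gulo alone had its highest level in hepatocyte-like cells in both sections. Glul was highest in endothelial-like cells in section 1 and in macrophage_kupffer-like cells in section 2. Bmp2, whose highest level was in endothelial-like cells, was lower at -1.12 (SE 0.35). In hepatocyte-like cells Epor, Car2, Bmp2 and Rnase4 each held fewer counts than the highest blank in all kept cells, in both sections. Cd24a, Mki67 and Cyp2f2 did so in section 2 only. By edgeR 16 of 337 genes passed, 9 higher and 7 lower, all with the same direction in both sections. Blood-forming-like cells were 22.3% of kept cells in section 1 and 9.56% in section 2, and erythroid-like cells alone 14.7% and 2.31%. Most such cells were thus erythroid-like in section 1 but monocyte_neutrophil-like in section 2, and no comparison used erythroid-like neighbours alone. In section 2 the monocyte_neutrophil-like class held 1181 cells, but 260 at resolution 2.0 and 0 at resolution 0.5 or scaled by volume. Clustered again with a minimum of 20 counts, it made up 7.11% of section 2. The comparison of neighbours was not rerun with classes from another clustering, so its bins in section 2 depend on the clustering used here. Of the 9 higher genes 8 had their highest level in erythroid-like cells in both sections, where Mki67 reached 640 and 330 counts per 10000 against 51.7 and 14.0 in hepatocyte-like cells. Of 16 pericentral genes 4 fell, and 5 when adjusted over the list alone (fry adjusted p = 0.23). Of 8 cell cycle genes 2 rose, and 2 rose and 1 fell when adjusted over the list alone (fry adjusted p = 0.33), and no list passed this one-way test. By fry's mixed test 5 of 16 lists passed, with gluconeogenesis at an adjusted p of 0.0025. Pericentral genes, cell cycle, blood niche signals and central endothelial genes passed it at 0.038 each. Gluconeogenesis and blood niche signals each had 0 of 7 members called by edgeR, also when adjusted over the list alone. Median and mean differed in sign for blood niche signals (0.04 and -0.22) and interferon genes (0.01 and -0.03), and for portal endothelial genes the median was 0.08 while fry pointed down. DESeq2 called 4 genes, and edgeR without the section as a block 0, with 3 at an unadjusted p under 0.05. With cell volume as the offset, which moved the median log2 change to 0.21, 25 genes were higher and 1 lower, and without TMM 15 and 4.

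**Figure D3:**
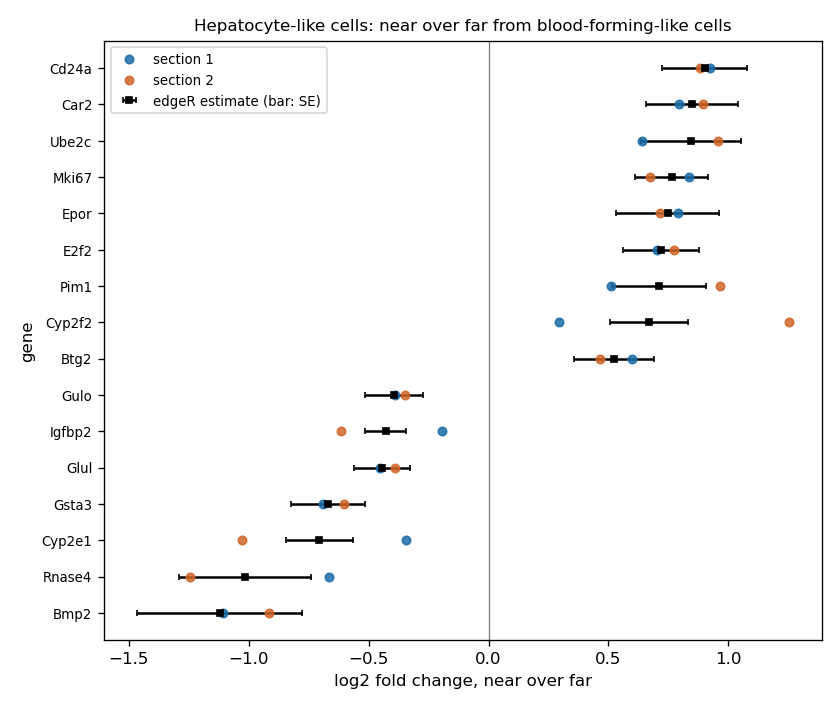
Log2 fold change (near over far from blood-forming-like cells) of the called genes in hepatocyte-like cells. Squares with bars are edgeR estimates with SE, and circles are the sections, with Cd24a at 0.90 and Rnase4 at -1.02.

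Stellate_mesenchymal-like cells neighboured their own class more often than in shuffles, with a log2 observed over expected of 2.71 in section 1 and 2.90 in section 2. Erythroid-like cells did so at 1.27 and 2.13. With labels shuffled only within 500 µm tiles these values were 1.43 and 2.03 for stellate_mesenchymal-like and 0.92 and 1.47 for erythroid-like cells. Pairs of hepatocyte-like and stellate_mesenchymal-like cells were rarer than in shuffles, at -0.58 and -0.88. Cell cycle genes reached 830 and 677 counts per 10000 in erythroid-like cells against 98.0 and 83.0 in hepatocyte-like cells. Unnamed cells stood at 155 and 403. Mki67 is on this list, and its levels given above make up a large part of the erythroid-like values. It was also among the leading genes of the erythroid-like cluster (11.2-fold), so the class was formed partly on it. With a minimum of 20 counts unnamed cells of section 2 reached 586 and erythroid-like cells 584. The 10 leading genes of the unnamed cluster held Cdk1 (9.41-fold), also on the cell cycle list, beside Wnt4 (41.1-fold), but not Mki67. The unnamed values were not computed without Cdk1, so they cannot be read as equal proliferation. Among single genes Cyp2f2 had a Moran's I of 0.353 in section 1 and 0.280 in section 2, and Col1a1 of 0.211 and 0.253. With 25 µm squares these values were 0.400 and 0.109 for Cyp2f2 and 0.181 and -0.0211 for Col1a1, and with 100 µm squares 0.142 and 0.180, and 0.175 and 0.282. In both sections 7 genes exceeded every blank barcode, whose highest values were 0.198 and 0.122, so others such as Hp, with 0.185 and 0.351, lay below the highest blank in section 1.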

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

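The tests of RNA from erythroid-like neighbours and of cell edges were chosen only after related results were seen, and the bins within position were added after the data were seen. No biological explanation that sets groups apart was tested, as the design has 1 group, and position in the lobule was tested for 1 pattern. Transcripts that lay in no segmented cell were used in no comparison, and they made up 40.4% of decoded transcripts in section 1 and 34.5% in section 2.

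Near blood-forming-like cells 8 genes with their highest level in erythroid-like cells, among them Cd24a and Mki67, were higher in hepatocyte-like cells, and the pericentral genes Rnase4, Cyp2e1, Glul and Gulo lower. RNA of neighbouring erythroid-like cells is a candidate explanation for the first part, from these values. The 29 tested genes at 5-fold or more in erythroid-like cells had a median log2 change of 0.39 (lower quartile 0.23). The other genes had -0.06, and the 21 of the 29 that were not called had 0.25 (lower quartile 0.07). Neighbours were not split by class, and most blood-forming-like cells of section 2 were monocyte_neutrophil-like. Transcripts at cell edges stay open, since the pooled share of counts within 4 µm of the centre was 0.925 percentage points above that of hepatocyte genes. The intervals overlapped in both sections (46.6% against 44.8%, and 34.9% against 34.8%). Single genes went both ways, with Pim1 above the reference at 55.3% and 47.2%. Car2 lay below it at 44.0% and 28.7%, beyond the intervals only in section 2. With only the transcripts within 4 µm, edgeR called 4 genes higher and 8 lower, against 9 and 7 with all transcripts. Of the 16 calls 7 were kept, but 241 genes were tested against 337. Bins within position left the 4 pericentral genes a median log2 change of -0.39 against -0.57, and as Glul, Cyp2e1 and Gulo are landmarks of that position, it cannot be told apart as their cause. Cyp2e1 went from -0.70 (SE 0.14) to -0.57 (SE 0.12) and still passed (edgeR adjusted p = 0.00020), while Glul went from -0.44 (SE 0.12) to -0.21 (SE 0.10), Gulo from -0.39 (SE 0.12) to -0.17 (SE 0.10) and Rnase4 from -1.02 (SE 0.28) to -0.60 (SE 0.26), and their calls ended with the smaller changes.

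Wnt2, Oit3, Col1a1 and Col3a1 were higher in pericentral-side hepatocyte-like cells. Their pooled counts lay within 4 µm of the centre less often than those of hepatocyte genes, by a mean of -6.40 percentage points (39.0% against 44.8% in section 1, and 27.8% against 34.8% in section 2). Wnt2, with 70 and 54 counts, stood at 51.4% and 29.6%, above the reference in section 1 only, with intervals that spanned it. Col1a1 was lowest, with 33.7% and 26.2%. The other 3 genes together lay below the reference too, with 42.7% (interval 38.8% to 46.7%) and 29.6% (25.4% to 34.0%), but beyond its interval only in section 2, so RNA at cell edges cannot be told apart as a cause for the set.

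The hepatocyte-like share was 29.7 percentage points lower in section 1 than in section 2. The first naming rule gave 43.7% and 39.1%, but these shares prompted the change of rule and so test nothing, and at resolution 2.0 under the rule used here the shares were 37.9% and 38.9%. With section 1 thinned to a median of 22 kept counts, against 15 in section 2, the gap had a median of -38.9 points and turned in 4 of 5 draws, in which most cells of section 2 stayed unnamed, so depth cannot be told apart from naming. Hepatocyte-like and unnamed cells together stayed more frequent in section 2 in all 5 draws, with 49.9% to 58.7% in section 1 and 76.6% to 84.9% in section 2.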

How the results depend on the processing

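The splits of hepatocyte clusters, the first naming rule and the bins within position were chosen after seeing the data, and the other alternatives before. All 30, 2 and 16 called genes kept their direction in each section alone, where no test was possible with 1 section left. Without the replicate block edgeR called 0 genes in all 3 comparisons (10, 0 and 3 at an unadjusted p under 0.05) and 2 lists passed for hepatocyte-like cells by position. That comparison (30 calls) gave 19 with DESeq2, 19 with at least 500 counts, 14 in the largest hepatocyte cluster alone, 4 in the others, 2 with periportal landmarks alone and 13 at 30 µm. Macrophage_kupffer-like cells (2 calls) gave 0 with DESeq2 (3 unadjusted), without TMM (13), with the volume offset (13), with at least 500 counts (0), with a minimum of 20 counts (9), at 30 µm (6) and with transcripts near the centre (3), 1 without a filter and 4 at 100 µm. Near blood-forming-like cells (16 calls) DESeq2 gave 4, the volume offset 26, the largest hepatocyte cluster 9, the others 1, a minimum of 20 counts 9 and 100 µm 6. The median depth was 3.50 without a minimum and 34 with 20. At resolution 0.5 B_lineage-like, macrophage_kupffer-like and monocyte_neutrophil-like cells stood at 0%, endothelial-like at 15.5% and unnamed at 0.160%. At resolution 2.0 hepatocyte-like cells stood at a mean of 38.4% (from 62.4%), monocyte_neutrophil-like at 3.32% and unnamed at 30.5%. Clustered again with a minimum of 20 counts, while the comparisons at that minimum kept the main class names, macrophage_kupffer-like cells stood at 0%, monocyte_neutrophil-like at 9.96% and unnamed at 1.39%, and scaled by volume B_lineage-like at 3.12%, monocyte_neutrophil-like at 0% and unnamed at 0.626%. The first naming rule gave a mean of 41.4% hepatocyte-like and 25.9% unnamed. By position at 30 µm the log2 ratio turned to 0.27 for B_lineage-like cells (from -0.54), with -0.46 in section 1 and 1.0 in section 2. It was 0.53 for endothelial-like (from 0.76), -0.51 for erythroid-like (from -0.62) and -0.59 for unnamed cells (from -0.05). At 100 µm it was 0.49 for endothelial-like and -0.96 for erythroid-like cells. For stellate_mesenchymal-like cells it turned at 100 µm to -0.013 (from 0.26), with 0.65 in section 1 and -0.68 in section 2. The cell cycle ratio of erythroid-like to hepatocyte-like cells (8.31) was 8.0 with a minimum of 20 counts and 5.85 per cell volume. Mki67 entered each of these ratios, and none was computed without it. Fewer cells or genes entered at 30 µm, with the higher minima and in parts of the clusters, and the cause was otherwise not tested. The alternatives for endothelial-like and stellate_mesenchymal-like cells were not run, since their comparisons were not.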

Other observations

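No test in this part was planned, and the values below were picked after they were seen. The Ttr stain had a median brightness per volume of 675490 in hepatocyte-like and 248732 in erythroid-like cells of section 1, but of 172703 and 165231 in section 2. The GFP stain was at 202117 and 182742 in section 1 and at 101380 and 101453 in section 2.

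In sections 1 and 2 Hp stood at 1029 and 1778 counts per 10000 in hepatocyte-like cells, 1077 and 2076 in monocyte_neutrophil-like cells and 462 and 716 in erythroid-like cells. The first focal plane held 47.5% of transcripts in section 1 and 30.6% in section 2.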
